A study of Mus musculus with 12 samples.

How the data were processed

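The study measured polyadenylated RNA from cultures of the mouse breast cancer line PB3, as 12 libraries in 4 groups of 3, Control (untreated parental cells), ERI-R, PAC-R and VIN-R (derivatives selected with eribulin, paclitaxel or vinorelbine at 300, 500 and 800 nM). Libraries were made from 200 ng of RNA with a Kapa mRNA HyperPrep kit and read as paired ends of 76 bases. Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 2.4, STAR 2.7.2b and RSEM 1.3.2 were used with GRCm38, without stated roles or order. The annotation and the strand setting are not given in the sources used here. The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples.

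Per the file headers, the authors deposited RSEM gene results, in which the expected count is an estimated number of read pairs per gene, not normalized and not always whole. Per the file headers, effective_length is the number of bases of a gene in which a fragment can start, and it was used only to read the mean fragment length of each library, which lay between 179 and 205 bases. The other columns were not used here. Each file held 55573 genes, of which 55394 had a symbol and 55480 a position in GENCODE M21 (GRCm38). All 804 symbols of the gene lists were matched. Totals of expected counts were 13454395, 12173141 and 11229321 in Control 1 to 3, 11189181, 11477429 and 11141028 in ERI-R, 11493830, 11937274 and 13347836 in PAC-R and 11927564, 11963411 and 13376686 in VIN-R. At these totals 3 counts, taken as the floor, correspond to between 0.223 and 0.269 CPM per library and to 0.0814 CPM over the 3 Control libraries. Floors and intervals cover counting error only.

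Expected counts were rounded, which changed 15.3% of the values above 0. Genes were filtered with filterByExpr on the groups, which kept 14226 genes (14220 with a symbol), and scaled by TMM. One edgeR 4.0.16 quasi-likelihood fit (glmQLFit, robust) held all 12 libraries with a mean per group (R 4.3.3, limma 3.58.1, the R package data.table at version 1.17.8). The prior count of the fit was left at edgeR's default, and a prior count of 1 was used only for log2 CPM. The fit had 8 residual degrees of freedom, a median of 2.64 prior degrees of freedom and a common biological coefficient of variation of 0.591. Each line was compared with Control and each line with the other lines, 6 comparisons in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, and genes changed at least 2-fold were counted beside it. CPM in the text are group means with SD over 3 libraries.

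The 31 gene lists covered epithelial junction and identity genes, transcription factors of the epithelial-mesenchymal transition, mesenchymal genes, collagens, mammary basal and luminal genes, tubulins, microtubule-associated proteins, ABC transporters and neighbours of Abcb1a and Abcb1b. They also covered detoxification, cell cycle, p53 targets, apoptosis, interferon-stimulated genes, antigen presentation, cytokines with NF-kB targets, TGF-beta, Wnt, YAP and actin-SRF targets, SWI/SNF subunits, histone and DNA methylation enzymes, hypoxia with glycolysis, cholesterol synthesis, unfolded protein and integrated stress responses, and growth factor receptors. The remaining lists were markers of fibroblasts, leukocytes, endothelial cells with pericytes, and adipocytes with erythroid and muscle cells, and the mitochondrially encoded genes. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, which compares a list with the other genes. Camera with an estimated correlation and fry were the alternatives. The directional p of fry tests whether the genes of a list move on balance in 1 direction and its mixed p whether they change in either direction, and neither compares the list with other genes.

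The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each line against Control, the 6 largest rises and 6 largest falls, and 4 and 4 between lines, among called genes with a mean of at least 5 CPM in the higher group and no overlap of libraries, leaving out predicted genes and pseudogenes. It added 21 genes named in each line against Control, up to 2 rises and 2 falls per list with a mean of at least 1 CPM, up to 6 and 6 genes called in all 3 lines, and 3 and 3 genes per line against all 3 other groups. Of the genes it takes, 3 are not reported here. Folds against groups with 0 counts are lower bounds from a floor of 3 counts over the group, and genes with 1 to 3 counts have a CPM ratio with a 95% counting interval. Fitted fold changes of such genes depend on the default prior count of the fit. Paralogs share reads, which affects Abcb1a with Abcb1b, the tubulins, and Prl2c2 with Prl2c3.

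The alternatives were DESeq2 size factors, total counts alone, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a fit of the 6 libraries compared, a replicate block with TMM or total counts, a test against a 1.5-fold change, unrounded counts, and leaving out each library. After seeing the data, a leukocyte marker score as a covariate and a fit of the 8 libraries with leukocyte transcripts were added. For the replicate numbers, a pairing was checked where every pair of libraries correlated above 0.1, which held for ERI-R against PAC-R (0.620, 0.607 and 0.764) and PAC-R against VIN-R (0.221, 0.751 and 0.917). In the 3 lines replicate 3 was the library without leukocyte transcripts, and for 5 of 12 libraries the best-correlated library of another group had the same number. With the replicate block ERI-R against PAC-R gave 2604 genes and PAC-R against VIN-R 0.

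The method was tested on simulated negative binomial counts of the same design, with 250 genes changed at each fold over 5 runs. In ERI-R, PAC-R and VIN-R against Control it recovered 0%, 0.4% and 0.4% of 2-fold changes, 12.4%, 13.2% and 13.2% of 4-fold changes, 49.2%, 50.4% and 48.4% of 8-fold changes and 72%, 74% and 68% of 16-fold changes, with 11, 10 and 7 false calls. Camera called the 1 list that was changed and 0 of 30 when none was. Simulated genes and libraries were drawn independently, so this could not test camera where genes of a list vary together. Simulated groups also lacked the division into libraries with and without leukocyte transcripts, although its spread was included. In the real data, splits that mixed the 2 groups gave up to 15 called lists. Within groups, the closest pair of libraries, ERI-R 1 and ERI-R 2, had a chi-square per degree of freedom of 42.5 over 13601 genes. Some pairs across groups were closer. The closest of all, PAC-R 1 and VIN-R 2, had 19.6 over 13092 genes, so no library was a duplicate. The sharing between lines that a common Control gives was simulated 20 times. The 3 Control libraries are too few to be divided between comparisons. For regions, 10700 genes were taken in 535 windows of 20 neighbours, and the SD of window medians was compared with 1000 shuffles of gene order.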

Results

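Polyadenylated RNA was sequenced from cultures of PB3, a mouse breast cancer cell line without estrogen receptor, progesterone receptor or HER2. The 12 libraries formed 4 groups of 3. Control was the untreated parental line. ERI-R, PAC-R and VIN-R were derivatives selected with 300, 500 and 800 nM of eribulin, paclitaxel or vinorelbine. All 3 drugs act on microtubules: paclitaxel stabilises them, while eribulin and vinorelbine block their growth. The series is presented as part of work on the mesenchymal-epithelial transition, epigenetic reprogramming and treatment response of breast cancers. Expected counts summed to between 11141028 and 13454395 per library. At these totals 3 counts correspond to between 0.223 and 0.269 CPM (the count scaled to a common library total) in a single library. Of 55573 genes, 14226 were tested.

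The libraries differed first in transcripts of macrophages and other leukocytes. Control 1, ERI-R 3, PAC-R 3 and VIN-R 3 had 0 CPM of Lyz2, the lysozyme of macrophages and granulocytes, while the other 8 libraries had between 186 and 1385 CPM. Ptprc, the pan-leukocyte antigen CD45, reached at most 0.0739 CPM in those 4 libraries and between 60.4 and 367 CPM in the other 8. Csf1r, the receptor for macrophage colony-stimulating factor, reached at most 0.775 CPM against 37.8 to 208 CPM. Transcripts of complement C1qa lay at 0 in the 4 and between 11.8 and 90.9 CPM in the 8. Each group therefore held 2 libraries with these transcripts and 1 without. The T-cell gene Cd3e, the endothelial gene Cldn5 and the erythroid gene Hbb-bs were at 0 CPM in all 12 libraries.

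Inflammatory gene groups moved with the leukocyte transcripts. Interferon-stimulated genes averaged between 1.55 and 2.32 log2 CPM in the 4 libraries without them and between 4.76 and 7.75 in the other 8. Antigen presentation genes averaged 1.40 to 2.56 against 4.16 to 6.24, and cytokines with other NF-kB targets 1.10 to 1.95 against 4.83 to 6.71. The acute-phase gene Saa3 reached at most 0.571 CPM in the 4 and at least 517 CPM in the 8, and Il6 at most 0.0772 CPM against at least 13.002. Mitochondrially encoded genes took between 1.503% and 2.45% of the counts in the 4 libraries and between 3.22% and 4.35% in the 8. ERI-R 3 stood further apart, with 15.4% of its counts in ribosomal protein genes against 3.62% to 6.07% in the 8, the lowest fitted fragment length (179 bases) and 3.40% in Gm42418, a locus that overlaps ribosomal RNA sequence.

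**Figure D1:**
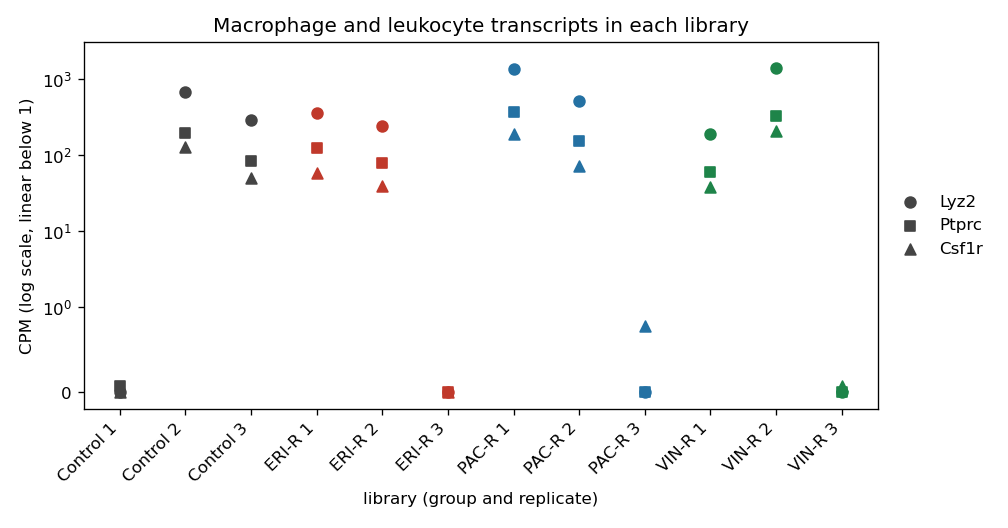
CPM of Lyz2, Ptprc and Csf1r in each of the 12 libraries, coloured by group, on an axis that is logarithmic above 1 and linear below. The 8 libraries with leukocyte transcripts lie between 37.8 and 1385 CPM, and Control 1, ERI-R 3, PAC-R 3 and VIN-R 3 lie under 1 CPM for all 3 genes.

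The first principal component of log2 CPM, with 48.1% of the variance, parted the 4 libraries without leukocyte transcripts (scores of -75.3 and below) from the other 8 (-6.05 and above). The second, with 36.8%, set the 3 ERI-R libraries (scores 120 to 139) apart from the other 9 (at most 9.24).

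**Figure D2:**
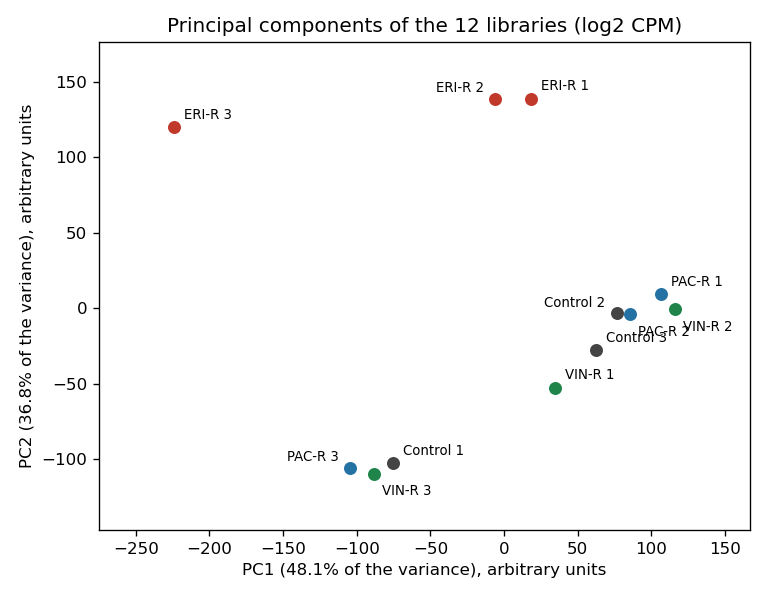
Scores of the 12 libraries on the first 2 principal components of log2 CPM, in arbitrary units, coloured by group. ERI-R lies between 120 and 139 on the second component, and the other 3 groups overlap.

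The eribulin-resistant line against the parental line asks which genes differ in cells selected with eribulin. ERI-R had higher levels of many epithelial and basal transcripts and lower levels of many mesenchymal transcripts than the parental cells. Cdh1, the junction protein E-cadherin, stood at 237 ± 124 CPM (SD, n = 3) in ERI-R and 10.6 ± 3.09 CPM (SD, n = 3) in Control, a log2 fold change of 4.48 (adjusted p = 0.0028). Vim, the mesenchymal filament vimentin, stood at 158 ± 130 CPM in ERI-R and 2965 ± 482 CPM in Control (SD, n = 3 each), a log2 fold change of -4.23 (adjusted p = 0.0036), which was -4.87 without ERI-R 1 and -3.56 without ERI-R 3. Of 14226 genes, 1353 were higher and 1379 lower in ERI-R, of which 1298 and 1305 differed at least 2-fold. The edgeR quasi-likelihood test was used, with Benjamini-Hochberg adjustment. The libraries of both groups did not overlap for 35.7% of genes, against 10% by chance. The 10% takes all libraries as exchangeable, which the division by leukocyte transcripts does not meet.

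Epithelial junction and identity genes rose together. Of 40 tested, 29 were higher and 1 lower (30 and 1 adjusted over the list alone), with a median log2 fold change of 4.58 (camera adjusted p = 1.2e-15, and adjusted p = 0.026 with an estimated correlation). Epcam, an epithelial adhesion molecule, stood at 235 ± 7.71 CPM against 7.65 ± 2.81 CPM (SD, n = 3 each), a log2 fold change of 4.94. Grhl2 and Ovol2, transcription factors that maintain epithelial identity, rose by 6.03 and 7.06, and Cdh3, P-cadherin, by 7.01. Ovol2 had 1 count over the 3 Control libraries, a CPM ratio of 184 (95% counting interval 33.1 to 7282). Esrp1, an epithelial splicing regulator, had a log2 fold change of 5.86, and its call was lost without Control 1 (5.79) or Control 3 (5.57). Krt8, a simple-epithelial keratin, was not called (477 ± 390 CPM against 826 ± 284 CPM, SD, n = 3 each), and its ERI-R mean was 257 CPM without ERI-R 3.

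Mammary basal and myoepithelial genes rose as well. Of 15 tested, 9 were higher and 1 lower, overall and adjusted over the list alone, with a median of 4.92 (camera adjusted p = 7.0e-05, and adjusted p = 0.026 with an estimated correlation). Krt14, a basal keratin, stood at 442 ± 423 CPM against 2.82 ± 2.55 CPM (SD, n = 3 each), a log2 fold change of 7.29. Without ERI-R 3 the ERI-R mean was 201 CPM and the log2 fold change 6.30. Krt17 had a log2 fold change of 7.03 (5.76 without ERI-R 3). The neurotrophin receptor Ngfr was the lower member. It had 2 counts over the ERI-R libraries, a CPM ratio of 64.1 between Control and ERI-R (95% counting interval 17.7 to 529). Mammary luminal genes went both ways, 7 higher and 4 lower of 19 (8 and 4 adjusted over the list alone), without a call for the list (median 2.17, camera adjusted p = 0.55). The mean of the luminal list lay at 3.14, 3.06 and 3.32 log2 CPM in ERI-R 1 to 3, against at most 2.23 in the other 9 libraries. Elf5, a regulator of alveolar cells, rose by 7.90. Gata3, which maintains luminal cells, and the EGFR ligand Areg had log2 fold changes of -2.70 and -2.27. Prlr, the prolactin receptor, had a log2 fold change of 6.89, and its call was lost without Control 3 (6.47).

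Mesenchymal genes fell. Of 32 tested, 16 were lower and 2 higher (17 and 3 adjusted over the list alone), with a median of -2.07 (camera adjusted p = 3.5e-06, but adjusted p = 0.28 with an estimated correlation). The median was -1.21 without Control 2. Cdh2, N-cadherin, had a log2 fold change of -4.80 and Fn1, fibronectin, of -2.72. The stromelysin Mmp3 and the crosslinking enzyme Loxl1 had -5.55 and -5.58, while the matrix proteoglycan Bgn rose by 3.28. The integrin chain Itgb3 had a log2 fold change of 1.57, and its call was lost without Control 1 (1.88), Control 2 (1.66), Control 3 (1.27) or ERI-R 1 (1.10). Among 19 transcription factors of the epithelial-mesenchymal transition, 7 were lower and 3 higher, overall and adjusted over the list alone (median -0.54, camera adjusted p = 0.060). Camera called them with a leukocyte marker score as a covariate (-0.61), in the 8 libraries with leukocyte transcripts (-0.79), both settings chosen after seeing the data, and without ERI-R 3 (-0.79). Zeb1, a repressor of Cdh1, had a log2 fold change of -3.96, Prrx1 of -5.34 and the chromatin protein Hmga2 of -5.47, and Msx1 rose by 3.35. The forkhead factor Foxq1 had a log2 fold change of 2.67, and its call was lost without Control 1 (2.74), Control 2 (2.37), Control 3 (2.96) or ERI-R 3 (1.74). Twist1 had a log2 fold change of -1.05. Its call was lost without Control 1 (-1.015), Control 2 (-1.02), Control 3 (-1.05), ERI-R 2 (-1.06) or ERI-R 3 (-0.69). Zeb2, Snai1 and Snai2 were not called (log2 fold changes -1.82, 0.43 and -1.49). With the score Zeb2 (-2.63, adjusted p = 0.010) and Snai2 (-1.68, adjusted p = 0.011) were called, and Snai2 also in the 8 libraries (-1.28, adjusted p = 0.048). Collagens were mixed, with 2 higher and 5 lower of 19 (3 and 6 adjusted over the list alone; median -0.89, camera adjusted p = 0.16). They were called in the 8 libraries (-0.51) and without Control 3 (-1.17). The basement-membrane chains Col4a1 and Col4a2 had -5.90 and -6.09, and Col11a1 and the hemidesmosomal Col17a1 rose by 5.31 and 4.48. YAP and actin-SRF targets fell, with 7 lower and 0 higher of 24 (10 and 1 adjusted over the list alone; median -1.29, camera adjusted p = 0.00049, but adjusted p = 0.39 with an estimated correlation). Fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, called the mesenchymal and YAP lists and the transition factors (adjusted p = 0.0016, 0.0025 and 0.0025). The YAP and actin-SRF targets included the receptor kinase Axl (-4.34) and the tropomyosin Tpm2 (-3.25).

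**Figure D3:**
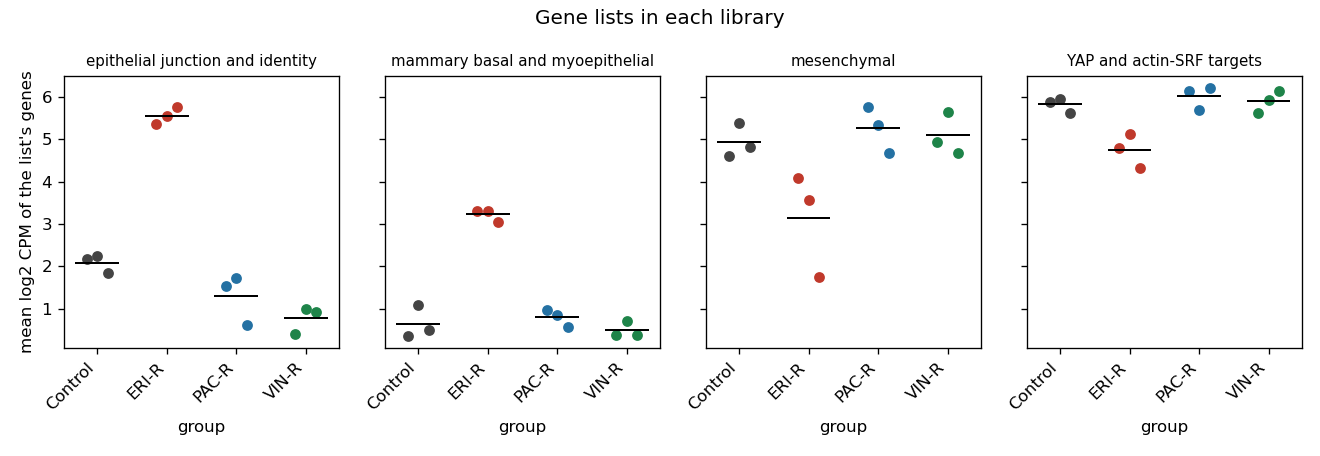
Mean log2 CPM of 4 gene lists in each library (points) with the mean of each group (lines). ERI-R lies between 5.35 and 5.77 for the epithelial list, against at most 2.25 in the other 9 libraries, and between 1.75 and 4.09 for the mesenchymal list, against at least 4.61.

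Genes of the drugs' targets and of drug export changed in both directions. Some of these lists also parted the 4 libraries without leukocyte transcripts from the other 8. Means lay at 2.36 to 2.94 against 3.13 to 3.77 log2 CPM for ABC transporters, 2.62 to 3.06 against 3.33 to 4.60 for the neighbours of Abcb1a and Abcb1b, and 3.65 to 4.03 against 2.78 to 3.47 for tubulins. Of 15 tubulins, 3 were higher and 2 lower, overall and adjusted over the list alone, and the list was not called (median 0.60, mean -0.07, camera adjusted p = 0.89). Tubb2b had a log2 fold change of -5.60. The alpha-tubulin Tuba8 had a log2 fold change of 3.03, and its call was lost without Control 2 (2.88) or Control 3 (2.90). Tubb3, the beta-tubulin isotype of neurons, stood at 7.14 ± 2.10 CPM in Control (SD, n = 3) and had 3 counts over the ERI-R libraries, a CPM ratio of 80.5 (95% counting interval 27.5 to 390). Tubb2a had a log2 fold change of 2.05, and its call was lost without Control 1 (2.18), Control 2 (2.14), Control 3 (1.86) or ERI-R 3 (1.3035). Tubb6 was not called (0.66). Of 30 microtubule-associated proteins, 3 were higher and 4 lower (4 and 4 adjusted over the list alone; median -0.28, camera adjusted p = 0.77). Map7 and the plus-end protein Mapre3 rose by 3.26 and 2.45, and Map1b and Map6, which stabilise microtubules, had -4.26 and -4.23. Of 23 ABC transporters, 2 were higher and 4 lower (5 and 5 adjusted over the list alone; median -0.37, camera adjusted p = 0.77). Abcb1a, a mouse gene for the drug efflux pump P-glycoprotein (chromosome 5, 8660077 to 8748575, GRCm38), stood at 2.76 ± 1.68 CPM in ERI-R and 20.9 ± 3.87 CPM in Control (SD, n = 3 each), a log2 fold change of -2.91. Its paralog Abcb1b was not called by edgeR, at 128 ± 70.2 CPM against 67.0 ± 5.98 CPM (log2 fold change 0.94, adjusted p = 0.089). The call was made without ERI-R 1 (1.16) or ERI-R 3 (1.31), with DESeq2 (adjusted p = 0.028), with the leukocyte marker score (0.91) and in the 8 libraries (1.19). Without ERI-R 2, the library at 209 CPM, the log2 fold change was 0.43 (adjusted p = 0.28). Abcc4 and Abcc1, further export pumps, had log2 fold changes of -2.88 and -1.73, and the Abcc1 call was lost without Control 1 (-1.49) or Control 3 (-1.77). Abcc1 had -1.10 in the 8 libraries. Abcb9 rose by 4.17. Abcb6 had a log2 fold change of 1.22, and its call was lost without Control 2 (1.06), Control 3 (1.16) or ERI-R 1 (1.21). Abcg2 was not called (-0.20, which turned to 0.13 without Control 1 and 0.22 without ERI-R 3). Of 14 neighbours of Abcb1a and Abcb1b on chromosome 5, 1 was higher and 3 lower (5 and 3 adjusted over the list alone; median 0.81, camera adjusted p = 0.84), with Steap2 at -2.30 and Cfap69 at -2.15. The metalloreductase Steap4 had a log2 fold change of 6.14, and its call was lost without Control 1 (5.71), Control 2 (7.27), Control 3 (6.02), ERI-R 1 (4.83) or ERI-R 2 (6.46). Close paralogs share reads, so the split between such genes depends on the assignment of shared read pairs.

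Signalling lists held large changes in both directions, and camera called none of them in the main fit, while fry called the TGF-beta and growth factor lists as lower (adjusted p = 0.0056 and 0.0024). Of 29 TGF-beta genes, 4 were higher and 9 lower (7 and 9 adjusted over the list alone; median -0.81, camera adjusted p = 0.44). The activin antagonist Fst stood at 71.0 ± 20.5 CPM against 2.03 ± 0.709 CPM (SD, n = 3 each), a rise of 5.12, Bambi rose by 3.49, and the transducer Smad3 had a log2 fold change of -3.19. The ligand Bmp4 had a log2 fold change of -3.30, and its call was lost without ERI-R 2 (-3.30). Of 26 Wnt genes, 7 were higher and 7 lower (8 and 8 adjusted over the list alone; median -0.59, camera adjusted p = 0.77). Nkd2, an inhibitor of Wnt signalling, and the ligand Wnt5b rose by 7.30 and 5.97. The receptor Ror2 had 3 counts over the ERI-R libraries, a CPM ratio of 139 (95% counting interval 47.5 to 674). The ligand Wnt7a had 1 count over the ERI-R libraries, a CPM ratio of 83.2 (95% counting interval 14.9 to 3286). Without Control 1 the ratio was 53.95. Of 24 growth factor receptors and ligands, 4 were higher and 9 lower (5 and 9 adjusted over the list alone; median -0.65, camera adjusted p = 0.12). The receptor Fgfr2, whose Control counts all lay in Control 2, rose by 7.27, and the ligand Fgf2 and the receptor Pdgfrb had -5.22 and -4.63. The stem cell factor receptor Kit had a log2 fold change of 5.25, and its call was lost without Control 1 (4.78), Control 3 (5.06), ERI-R 1 (4.91) or ERI-R 2 (5.10). Of 30 cytokines and NF-kB targets, 1 was higher and 4 lower, overall and adjusted over the list alone (median -0.80, camera adjusted p = 0.19). They were called in the 8 libraries (-0.74) and without Control 1 (-1.01). Cxcl12 and Csf2 had -5.22 and -4.96, and Ccl20 rose by 5.61.

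Stress, metabolic and chromatin lists held called genes as well. Of 25 detoxification genes and NRF2 targets, 5 were higher and 1 lower (8 and 2 adjusted over the list alone; median 0.51, camera adjusted p = 0.44). The quinone reductase Nqo1 rose by 5.37, and the UDP-glucose dehydrogenase Ugdh had -2.51. The cytochrome Cyp1b1 had a log2 fold change of 3.93, and its call was lost without Control 1 (3.89) or Control 3 (3.75). Of 25 apoptosis regulators, 0 were higher and 3 lower, overall and adjusted over the list alone (median -0.41, camera adjusted p = 0.44), among them the BH3-only gene Bmf (-2.53). This list parted the same libraries, at 3.37 to 3.73 against 4.52 to 5.29 log2 CPM. Of 24 p53 targets, 3 were higher and 0 lower, overall and adjusted over the list alone (median 0.88, camera adjusted p = 0.16), with Perp at 1.62. The endoplasmic reticulum gene Ei24 had a log2 fold change of 1.37, and its call was lost without Control 2 (1.34) or Control 3 (1.32). Of 26 genes of the unfolded protein and integrated stress responses, 1 was higher and 3 lower, overall and adjusted over the list alone (median -0.71, camera adjusted p = 0.11, fry adjusted p = 0.0025; called in the 8 libraries at -0.57), with Nupr1 at -2.10. The mTORC1 inhibitor Ddit4 had a log2 fold change of 1.08, and its call was lost without Control 1 (1.19), Control 2 (1.05), Control 3 (1.03) or ERI-R 1 (1.11). The serine synthesis enzyme Psat1 had a log2 fold change of -1.21, and its call was lost without Control 1 (-1.09). Of 26 SWI/SNF subunits, 2 were higher and 0 lower (1 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.77). The ATPase Smarca2 rose by 2.32, and the ATPase Smarca4 was not called (0.64, which turned to -0.27 without ERI-R 3). Smarcd2 had a log2 fold change of 0.89, and its call was lost without Control 2 (0.88), Control 3 (0.76) or ERI-R 2 (0.95). Of 39 histone and DNA methylation enzymes, 3 were higher and 2 lower, overall and adjusted over the list alone (median -0.22, camera adjusted p = 0.77), with the DNA methyltransferase Dnmt3b at 1.93 and the demethylase Kdm1a at -1.09. The DNA demethylase Tet1 had a log2 fold change of 3.49, and its call was lost without Control 1 (3.44) or Control 2 (3.29). The histone methyltransferase Kmt2a had a log2 fold change of -1.37, and its call was lost without Control 1 (-1.26), Control 3 (-1.26), ERI-R 2 (-1.24) or ERI-R 3 (-1.05). Cell cycle genes had 3 higher of 40 (0 adjusted over the list alone; median 0.02, camera adjusted p = 0.77). The thymidylate synthase gene Tyms had a log2 fold change of 2.34, and its call was lost without Control 2 (2.41) or Control 3 (2.07). The survivin gene Birc5 had a log2 fold change of 1.88, and its call was lost without Control 1 (2.05), Control 2 (2.03), Control 3 (1.62) or ERI-R 3 (1.44). Hypoxia and glycolysis genes had 2 higher of 27 and cholesterol synthesis genes 1 lower of 23, overall and adjusted over the list alone (medians -0.15 and -0.25, camera adjusted p = 0.77 for both). The aldolase Aldoc had a log2 fold change of 2.61. The mitochondrial gene Higd1a had a log2 fold change of 2.25, and its call was lost without Control 3 (1.96). Mitochondrially encoded genes had 1 higher of 15 (0 adjusted over the list alone; median -0.24, mean 0.04, camera adjusted p = 0.84). The complex I gene mt-Nd6 had a log2 fold change of 1.85, and its call was lost without Control 1 (1.78), Control 2 (1.99) or Control 3 (1.79). Without ERI-R 3 it was 0.97, still called.

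Interferon-stimulated and antigen presentation genes, which moved with the leukocyte transcripts between libraries, had 0 called members of 37 and 21 (medians 0.05 and -0.19, camera adjusted p = 0.77 for both). Macrophage and leukocyte markers had 0 of 17 (median -0.61, camera in the upward direction, adjusted p = 0.93). Fibroblast markers had 1 lower of 7 (Pdgfrb), overall and adjusted over the list alone (median -0.71, camera adjusted p = 0.58). Endothelial and pericyte markers had 1 higher, Mcam (2.71), and 1 lower, Rgs5 (-4.92), of 7, overall and adjusted over the list alone (median -0.70, camera adjusted p = 0.77). Only 1 adipocyte, erythroid or muscle marker was tested, at -0.13, so that list had no test.

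The largest rises by the rule for naming genes were in genes at or near 0 in Control. Kng2 (a kininogen), Cited1 (a transcriptional coregulator), Shisa8 and Fndc1 had 0 counts over the 3 Control libraries. Against a floor of 3 counts over that group they were at least 89.3-fold, 88.1-fold, 67.7-fold and 64.8-fold higher in ERI-R. A single library carried much of each mean. Without ERI-R 3 the bounds of Kng2, Cited1 and Shisa8 were 59-fold, 24.8-fold and 22-fold, and without ERI-R 1 that of Fndc1 was 19-fold. DESeq2 did not call Kng2 or Cited1. Spink5, a protease inhibitor of stratified epithelia, stood at 35.3 ± 17.5 CPM in ERI-R (SD, n = 3) and had 2 counts over Control, a CPM ratio of 651 (95% counting interval 180 to 5374). Gdf5, a BMP-family ligand, had 1 count over Control, a CPM ratio of 652 (95% counting interval 117 to 25765). Without ERI-R 3 the ratio was 420. In the other direction the placental lactogen gene Prl3d2, the homeobox gene Lhx8 and the retinoic acid-binding protein gene Crabp1 had 0 counts over ERI-R. They were at least 86.0-fold, 59.2-fold and 57.5-fold lower in ERI-R than in Control. Without Control 1 the bounds of Prl3d2 and Crabp1 were 33.7 and 31.2. Ildr2, a tricellular-junction protein gene, had a log2 fold change of -7.76. The acyl-CoA synthetase gene Acsl6 and the transcription factor gene Pax6 had 2 and 1 counts over ERI-R, CPM ratios of 242 (95% counting interval 66.9 to 1994) and 228 (40.8 to 8986).

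The number of calls against Control differed between fits, for reasons that were not tested. With a leukocyte marker score as a covariate, a setting chosen after seeing the data, 4533 genes were called, including all 2732. In the 8 libraries with leukocyte transcripts, a subset also chosen after seeing the data, 3264 were called, including 2351 of the 2732, and a fit of only the 6 libraries of both groups called 1744. Among the named genes, the fit of 6 libraries ended the calls of Foxq1, Itgb3, Tubb2a, Abcb6, Ugdh, Birc5, Perp, Ei24, Smarcd2, Kmt2a, Higd1a, Ddit4, Psat1, mt-Nd6, Abcc1 and Twist1, and the 8 libraries ended those of Foxq1, Tubb2a, Birc5, Kmt2a, Aldoc, Higd1a, Ddit4, mt-Nd6 and Twist1. The test against a 1.5-fold change ended those of Itgb3, Tubb2a, Abcb6, Birc5, Smarcd2, Kmt2a, Ddit4, mt-Nd6 and Twist1, and the replicate block those of Itgb3, Tubb2a, Smarcd2 and mt-Nd6. Without a filter on low counts Itgb3, Abcb6, Steap4, Smarcd2, Ddit4 and Twist1 were not called, and limma-voom did not call Tubb2a or mt-Nd6. Total counts without a composition factor ended the calls of Abcc1 and Twist1, and the replicate block with total counts those of Itgb3, Smarcd2, Kmt2a, Abcc1 and Twist1.

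Single libraries also set the size of many named changes. Of 87 named genes called against Control with more than 3 counts in each group, the fold change moved by over 1.5 times in 31 without ERI-R 3 (27 of them toward no change), 19 without ERI-R 1 (3), 11 without Control 2 (0) and 5 without Control 1 (5), and in 0 without ERI-R 2 or Control 3. None turned direction. Beside those given above, the smaller log2 fold changes without ERI-R 3 were those of Ildr2 (-7.17), Msx1 (2.38), Hmga2 (-4.77), Prrx1 (-4.63), Loxl1 (-4.91), Mmp3 (-4.93), Col4a2 (-5.40), Col4a1 (-5.19), Abcb9 (3.28), Abcc4 (-2.29), Ugdh (-1.91), Csf2 (-4.27), Wnt5b (5.05), Higd1a (1.54), Fgf2 (-4.56), Rgs5 (-4.26), Zeb1 (-3.29), Cdh2 (-4.14), Dusp9 (-5.81), Msln (-5.75) and Wfdc18 (6.81). Without ERI-R 1 they were those of Steap4 (4.83), Ccl20 (4.07) and Tet1 (2.87), and without Control 1 they included Col4a2 (-5.50), Pdgfrb (-3.70), Dusp9 (-5.84) and Msln (-5.68).

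**Figure D4:**
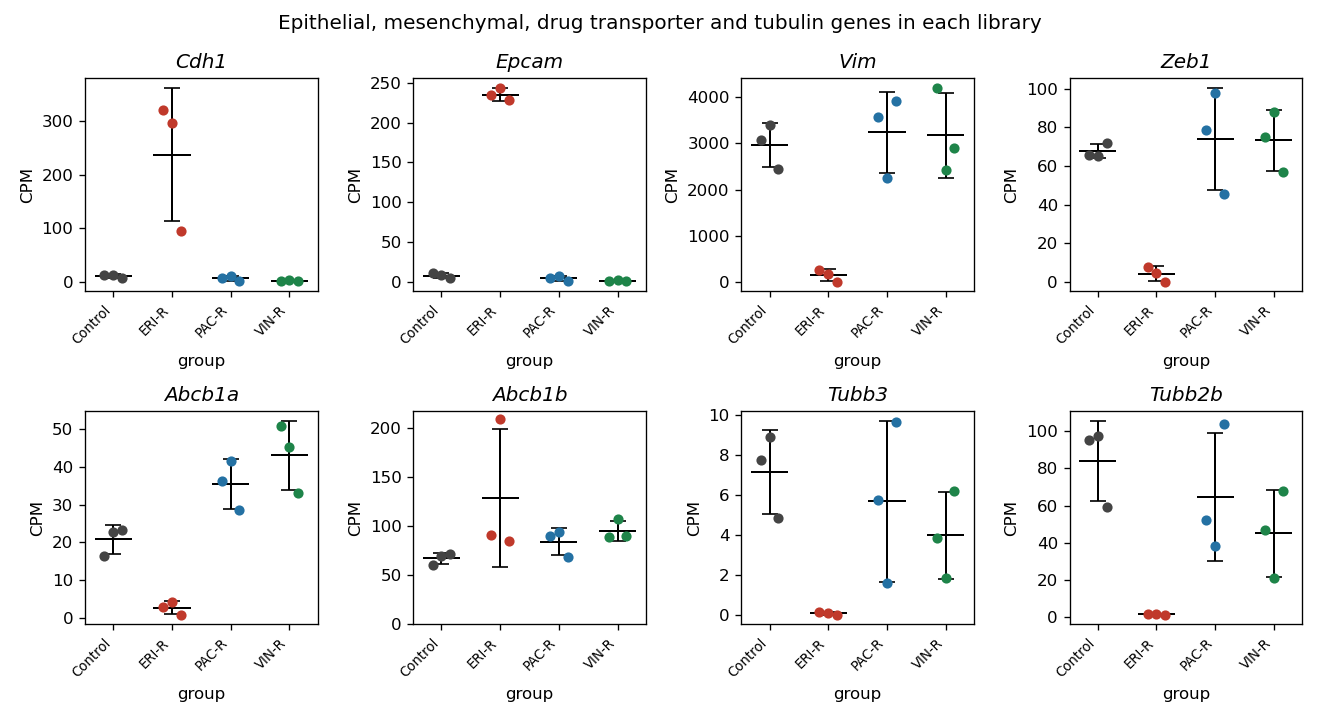
CPM of 8 genes in each library (points) with the mean and SD of each group of 3 (lines and bars), on linear axes. Cdh1 and Epcam are higher in the 3 ERI-R libraries than in the other 9, and Vim, Zeb1, Abcb1a, Tubb3 and Tubb2b are lower. Abcb1b overlaps less clearly, with 1 ERI-R library at 209 CPM.

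The paclitaxel-resistant line against the parental line asks which genes differ in cells selected with paclitaxel. Among 14226 genes edgeR called 0. This does not show that the lines are alike, since in simulated data of this design edgeR recovered 0.4% of 2-fold, 13.2% of 4-fold and 50.4% of 8-fold changes. The simulated groups lacked the division by leukocyte transcripts, so recovery in the real data may differ. The 21 genes named in every comparison were all uncalled (adjusted p = 1.00 each). Abcb1a stood at 35.4 ± 6.53 CPM against 20.9 ± 3.87 CPM in Control (SD, n = 3 each), a log2 fold change of 0.76. Vim stood at 3242 ± 873 CPM against 2965 ± 482 CPM, Cdh1 at 6.14 ± 4.21 CPM against 10.6 ± 3.09 CPM, and Tubb3 at 5.66 ± 4.02 CPM against 7.14 ± 2.10 CPM (SD, n = 3 each). At an unadjusted p under 0.05 edgeR gave 245 genes, where 711 are expected by chance, the smallest adjusted p was 0.192, limma-voom called 0 and DESeq2 24. The groups did not overlap for 7.58% of genes, against 10% by chance. Both chance values take all libraries as exchangeable, but each group held libraries with and without leukocyte transcripts. Genes that follow this division can hardly separate such groups and add to the spread within them. Values below chance therefore do not show that the groups are alike. The DESeq2 calls included the caveolar protein gene Cavin1 (3.16), the calcium channel subunit gene Cacna1c (4.26), Acsl6 (-2.72), Pax6 (-2.999), the sarcoglycan gene Sgce (-1.73) and Prl3d2 (-6.58), chosen after their values were seen. With the leukocyte marker score as a covariate edgeR called 3 genes, the annexin gene Anxa8 (2.25), Cacna1c (4.13) and Prl3d2 (-6.37).

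Of 30 lists tested in PAC-R against Control, camera called 6, and 0 of these held with an estimated correlation or with fry. Epithelial genes were lower, with 0 called of 40, a median of -0.61 and adjusted p = 1.1e-11 (adjusted p = 0.11 with an estimated correlation). Interferon-stimulated genes were higher (median 1.26, adjusted p = 2.6e-07, but 0.84 with an estimated correlation), as were antigen presentation genes (0.83, adjusted p = 8.0e-04, but 0.89 with an estimated correlation). Both lists follow the leukocyte transcripts, and PAC-R 1 had 1340 CPM of Lyz2 against at most 679 in Control. Without PAC-R 1 their medians were 0.14 and -0.08, and without Control 1 they were 0.74 and 0.34, each without a call. Without Control 2 they were 2.58 and 1.79, with the leukocyte marker score 0.58 and 0.45, and with the replicate block -0.15 and 0.47, each with a call in the upward direction. The antigen presentation median was 1.33 without PAC-R 3. Collagens were higher (median 0.37, adjusted p = 0.012, but 0.74 with an estimated correlation), and the call was lost without Control 3 (0.11) or PAC-R 1 (0.22). It was kept without Control 1 (0.74) or Control 2 (0.59) and with the replicate block (0.17). Wnt genes and histone and DNA methylation enzymes were lower (medians -0.19 and -0.15, adjusted p = 0.026 and 0.018, but 0.42 and 0.84 with an estimated correlation). Without Control 1 (-0.18 and -0.12) or PAC-R 1 (-0.22 and -0.16) neither was called. The Wnt call was also lost without PAC-R 2 (-0.10) and the enzyme call without PAC-R 3 (-0.08). The leukocyte marker score ended the Wnt call (-0.31) and the 8 libraries the enzyme call (-0.03). Called Wnt medians were -0.32 with the replicate block, -0.29 in the 8 libraries and -0.31 without PAC-R 3, and the called enzyme median was -0.30 without PAC-R 2. The number of lists called was 3 without Control 1, 12 without Control 2, 10 without Control 3, 1 without PAC-R 1 and 11 without PAC-R 3. In each of the 6 lists 0 members were called, also adjusted over the list alone.

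The vinorelbine-resistant line against the parental line asks which genes differ in cells selected with vinorelbine. VIN-R had lower values of epithelial genes than the parental line, although edgeR called 0 single genes. Cdh1 stood at 1.75 ± 1.41 CPM against 10.6 ± 3.09 CPM in Control and Epcam at 1.05 ± 0.994 CPM against 7.65 ± 2.81 CPM (SD, n = 3 each), log2 fold changes of -2.60 and -2.88 (adjusted p = 1.00). Without VIN-R 2 the VIN-R means were 0.94 and 0.472 CPM. Of 40 epithelial genes, 0 were called, also adjusted over the list alone, and the median was -1.82. It was -1.73 with the 3 members at 0 in a group set to their bounds. Camera called the list (adjusted p = 1.3e-26, and adjusted p = 0.0086 with an estimated correlation), but fry did not (adjusted p = 0.050). Wnt genes were lower (median -0.45, adjusted p = 9.5e-04, but 0.074 with an estimated correlation), with 0 called of 26, also adjusted over the list alone. The number of lists called was 4 without Control 1, 9 without Control 2, 7 without Control 3 and 11 without VIN-R 2 or without VIN-R 3. Abcb1a stood at 43.0 ± 9.08 CPM against 20.9 ± 3.87 CPM, a log2 fold change of 1.04, and Abcb1b at 95.4 ± 10.3 CPM against 67.0 ± 5.98 CPM, 0.51 (SD, n = 3 each; adjusted p = 1.00 for both). Vim was at 3174 ± 914 CPM and Tubb2b at 45.2 ± 23.4 CPM against 83.9 ± 21.4 CPM (SD, n = 3 each).

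Beside the 0 calls in VIN-R against Control, edgeR gave 381 genes at an unadjusted p under 0.05, where 711 are expected by chance, with a smallest adjusted p of 0.340. Limma-voom called 0 genes and DESeq2 36. The groups did not overlap for 8.55% of genes, against 10% by chance. The limit of the chance values given for PAC-R holds here too. The DESeq2 calls included Ildr2 (-2.95), Sgce (-2.52), the death receptor family gene Tnfrsf26 (2.19), the non-muscle myosin gene Myh10 (-1.82), Cacna1c (3.8025) and the peptide hormone gene Cck (3.70), chosen after their values were seen. With the leukocyte marker score as a covariate edgeR called 8 genes, namely Cck (4.10), Cacna1c (3.71), Tnfrsf26 (2.17), Myh10 (-1.81), Ildr2 (-2.92), Fermt1 (-2.08), Zfp618 (-3.22) and Prl3d2 (-3.85). In simulated data of the same design, with 250 genes changed at each fold, edgeR recovered 48.4% of 8-fold and 13.2% of 4-fold changes in VIN-R and 50.4% and 13.2% in PAC-R. The limit of these simulations given for PAC-R holds here too.

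No gene was called in the same direction in all 3 lines against Control by edgeR, and 0 shared calls are expected from independent lists of these sizes, since 2 of the lists were empty. DESeq2 gave 6 shared genes, Cacna1c higher and Sgce, Acsl6, Pax6, Myo5c and Megf6 lower, chosen after their values were seen. The leukocyte marker score as a covariate gave 2, Cacna1c (5.10, 4.13 and 3.71 in ERI-R, PAC-R and VIN-R) and Prl3d2 (-6.37 and -3.85 in PAC-R and VIN-R, and 0 counts in ERI-R). Without ERI-R 3 the count was 2, Cacna1c and C130074G19Rik. Across genes, which are not independent replicates, the fold changes of PAC-R and VIN-R correlated with r = 0.648 and had the same sign in 81.5% of genes. In simulations where both lines shared the 3 Control libraries without any true change, r averaged 0.495 and the sign matched in 66.7%, while the covariance averaged 0.364 against 0.231 observed. For ERI-R, r was 0.243 with PAC-R and -0.0357 with VIN-R, against simulated means of 0.502 and 0.499. The simulated spread included the difference between libraries with and without leukocyte transcripts. Simulated libraries were drawn independently, whereas each real group held both kinds of library. The simulations therefore cannot say how much of the observed r or sign match comes from the shared Control.

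The eribulin-resistant line against the paclitaxel-resistant line asks which genes differ between these 2 lines. ERI-R against PAC-R gave 1308 higher and 1359 lower genes. Mia, a secreted cartilage and melanoma protein gene, Lypd3, a cell-surface gene of stratified epithelia, and Kng2 had 0 counts over PAC-R. They were at least 298-fold, 100.2-fold and 89.1-fold higher in ERI-R. Without ERI-R 3, which had the most of each, the bounds were 63.6, 54.2 and 58.9. Wfdc18, a secreted whey acidic protein-domain gene, stood at 759 ± 972 CPM against 2.39 ± 2.00 CPM (SD, n = 3 each), and its call was lost without PAC-R 1 (8.70) or PAC-R 2 (8.70). Without ERI-R 3 the ERI-R mean was 200 CPM and the log2 fold change 6.56 in place of 8.31. In the other direction lay Cck (-7.01), the growth hormone-related Prl2c2 (-6.89) and the caveolar Cavin3 (-6.63). Cck and Prl2c2 had -6.07 and -5.89 without PAC-R 3, and Prl2c2 and Cavin3 -6.29 and -6.02 without ERI-R 3. The matrix gene Tnxb had 2 counts over ERI-R, a CPM ratio of 211 (95% counting interval 58.4 to 1741). It was 66.8 without PAC-R 3.

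Among 30 lists tested in ERI-R against PAC-R, camera called 8. Epithelial genes (30 higher, 0 lower of 40, and 33 and 1 adjusted over the list alone; median 5.41) had adjusted p = 1.3e-22 and 0.0065 with an estimated correlation. Basal genes (10 higher, 1 lower of 15, overall and adjusted over the list alone; median 3.31) had adjusted p = 2.6e-05 and 0.015 with an estimated correlation. Mesenchymal genes (1 higher, 16 lower of 32, and 2 and 18 adjusted over the list alone; median -2.18), YAP and actin-SRF targets (0 and 7 of 24, overall and adjusted over the list alone; median -1.33) and collagens (3 and 8 of 19, and 3 and 10 adjusted over the list alone; median -1.73) were lower (adjusted p = 5.5e-08, 4.4e-04 and 0.012). These calls were lost with an estimated correlation (adjusted p = 0.14, 0.37 and 0.48). The YAP median was -0.77 in the 8 libraries and -0.87 without ERI-R 3, both called. Transition factors (median -0.47), cytokines (-1.65) and unfolded protein genes (-0.92) each had adjusted p = 0.040, and 0.41, 0.86 and 0.32 with an estimated correlation. The transition factor call was lost without ERI-R 2 (-0.30), PAC-R 2 (-0.47) or PAC-R 3 (-0.46), and its median was -1.06 without ERI-R 1. The cytokine list, which moved with the leukocyte transcripts, lost its call without ERI-R 3 (-0.99), PAC-R 1 (-0.46) or PAC-R 2 (-1.70). With the leukocyte marker score its median was -0.30 without a call (adjusted p = 0.14), and fry did not call it (adjusted p = 0.25). The unfolded protein call was lost without ERI-R 2 (-0.76), with the replicate block (-0.94, adjusted p = 0.054) and with the leukocyte marker score (-0.88, adjusted p = 0.055), and kept without ERI-R 3 (-0.61).

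ERI-R against VIN-R gave 1358 higher and 1386 lower genes. Tmem54, the epithelial ubiquitin ligase gene Cblc, Mia and Cdkn2a, which encodes the cell cycle inhibitor p16 and ARF, had 0 counts over VIN-R. They were at least 399-fold, 325-fold, 302-fold and 276-fold higher in ERI-R. Without ERI-R 3, which had the most of each, the bounds were 157, 112, 64.4 and 130. Cck, the phosphatase gene Dusp9 and mesothelin, Msln, had log2 fold changes of -8.85, -6.96 and -6.95, and Tnxb a CPM ratio of 173 (95% counting interval 47.9 to 1429), which was 90.4 without VIN-R 3. Dusp9 and Msln had -6.27 and -6.08 without VIN-R 3. Camera called 5 of 30 lists. Epithelial genes (32 higher, 0 lower of 40, and 32 and 2 adjusted over the list alone) had a median of 6.397, or 5.99 with 3 members at their bounds, and adjusted p = 4.0e-23 (0.018 with an estimated correlation). Basal genes (10 higher, 1 lower of 15, overall and adjusted over the list alone; median 2.82) had adjusted p = 5.8e-05 (0.019 with an estimated correlation). Mesenchymal genes (median -2.05), YAP and actin-SRF targets (-1.16) and transition factors (-0.74) were lower with adjusted p = 1.2e-06, 9.8e-04 and 0.025. These calls were lost with an estimated correlation (adjusted p = 0.22, 0.40 and 0.39), and the last also without ERI-R 2 (-0.52) or VIN-R 1 (-0.59). The transition factor median was -1.21 without ERI-R 1 and the YAP median -0.75 in the 8 libraries, both called. In all, 1100 genes were higher and 1137 lower in ERI-R than in each of Control, PAC-R and VIN-R, in 3 comparisons that share the ERI-R libraries, while PAC-R and VIN-R had 0 genes that differed from all 3 other groups. Those named by the rule were Kng2, Mia and Wfdc18 among the higher and Lhx8, Dusp9 and Msln among the lower genes. Against Control, Mia had 2 counts over the Control libraries, a CPM ratio of 448 (95% counting interval 124 to 3696), which was 95.5 without ERI-R 3. The call of Mia was lost without any 1 of the 3 Control libraries. Wfdc18 had a log2 fold change of 8.59 against Control, lost without Control 3 (8.15), and Dusp9 and Msln had -6.42 and -6.37.

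PAC-R and VIN-R were not told apart by single genes, as edgeR called 0 (156 at an unadjusted p under 0.05, 711 expected by chance, smallest adjusted p 1.00), limma-voom 0 and DESeq2 5. The 5 were higher in PAC-R, namely Cavin1 (2.77), Adgrf5 (2.196), Col23a1 (3.71), the collagen chaperone gene Serpinh1 (1.73) and Ildr2 (1.64), chosen after their values were seen. The groups did not overlap for 3.20% of genes, against 10% by chance. As for PAC-R against Control, values below chance do not show that the lines are alike. Camera called 4 of 30 lists, all higher in PAC-R. Endothelial and pericyte markers (median 0.72, 0 called of 7, 1 adjusted over the list alone) had adjusted p = 2.3e-06 and 0.033 with an estimated correlation. Their median was 0.14 without PAC-R 1, 0.33 without VIN-R 1, 1.70 without VIN-R 2, 0.27 without VIN-R 3 and 0.47 in the 8 libraries, each with a call. Epithelial genes (median 0.83, 0 called of 40, also adjusted over the list alone) and collagens (0.53, 0 of 19, 1 adjusted over the list alone) had adjusted p = 1.2e-07 and 5.4e-09, but both 0.15 with an estimated correlation. The epithelial median was 0.53 without PAC-R 1, 0.47 without PAC-R 2 and 0.48 without VIN-R 1. The collagen median was 0.33 without PAC-R 1, 0.98 without PAC-R 3 and 1.17 without VIN-R 2. All of these medians were called. The epithelial order was reversed between the libraries without leukocyte transcripts, with list means of 0.619 log2 CPM in PAC-R 3 and 0.913 in VIN-R 3. With leukocyte transcripts, PAC-R 1 and 2 had 1.53 and 1.73, against 0.41 and 0.995 in VIN-R 1 and 2. Interferon-stimulated genes (0.50, 0 of 37, also adjusted over the list alone) had adjusted p = 0.0014, but 0.98 with an estimated correlation. Their median was -0.62 without PAC-R 1, 0.64 without PAC-R 2, 0.11 without VIN-R 1 and -0.0081 without VIN-R 3, each without a call, and 1.08 without PAC-R 3 and 2.92 without VIN-R 2, both called. Fry called 0 lists. The number of lists called by camera was 8 without PAC-R 2, 10 without PAC-R 3, 13 without VIN-R 2 and 10 without VIN-R 3.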

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

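The splits, the constancy of marker ratios and the tests along chromosomes were chosen before their results were seen. The score covariate, the fits without ERI-R 3, both counts of genes at the floor, the depth and group tests of the leukocyte transcripts, and all tests of Cdkn2a, Cdkn2b and Mtap were chosen only after.

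ERI-R differed from the other resistant lines in direct tests between lines, which drew attention to these results. Against PAC-R 2667 genes were called and against VIN-R 2744, with 13 of the 21 always-named genes called in each. The log2 fold changes against PAC-R were Abcb1a -3.67, Abcc1 -1.76, Cdh1 5.27, Epcam 5.89, Esrp1 6.35, Grhl2 5.59, Zeb1 -4.09, Twist1 -1.30, Vim -4.35, Cdh2 -4.26, Fn1 -2.51, Tubb3 -5.95 and Tubb2b -5.22. Against VIN-R they were Abcb1a -3.95, Abcc1 -1.88, Cdh1 7.08, Epcam 7.82, Esrp1 8.42, Grhl2 7.84, Zeb1 -4.08, Twist1 -1.32, Vim -4.32, Cdh2 -4.56, Fn1 -2.55, Tubb3 -5.43 and Tubb2b -4.71. Groups of 3 were too small for a test of single outlying libraries.

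With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real splits gave 2732, 0, 0, 2667, 2744 and 0 genes in ERI-R, PAC-R and VIN-R against Control, ERI-R against PAC-R, ERI-R against VIN-R and PAC-R against VIN-R, and the highest other split gave 0 in each. Counts as large came from 1, 10, 10, 1, 1 and 10 of the splits, the real one included. For lists called by camera the real counts were 4, 6, 2, 8, 5 and 4, the highest others 10, 12, 15, 11, 11 and 12, and the splits as large 10, 8, 10, 5, 8 and 10. The split of PAC-R 1, PAC-R 2 and VIN-R 2 against VIN-R 1 and the libraries without leukocyte transcripts, PAC-R 3 and VIN-R 3, gave 3260 genes at an unadjusted p under 0.05 against 156 in the real split. This points to a structure of the samples other than the lines.

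Leukocyte transcripts were present in 8 of 12 libraries. All 4 groups held libraries of both kinds, which argues against the line or its selection as the cause. Depth is argued against as well, since 3 counts in the smallest of the 4 libraries without them allow 0.269 CPM, while Lyz2 reached at least 186 CPM in the other 8. Over those 8, the median SD of a marker's log2 ratio to the list mean was 0.149 against 1.08 for the list mean, with 17 of 17 markers below it, so RNA of macrophages mixed into the samples is a candidate explanation. Whether such cells or their RNA entered in culture, at harvest or later was not tested, and no sort is described in the labels. The mitochondrial share of the counts, also higher in the 8, did not rise with Lyz2 among them. It was 4.35% in VIN-R 1, with 186 CPM of Lyz2, but 3.22% and 3.85% in PAC-R 1 and VIN-R 2, with 1340 and 1385 CPM. Whether both kinds of library also differed in another way, such as a batch, was not tested.

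Epithelial genes were higher and mesenchymal genes lower in ERI-R than in Control. The epithelial median stayed at 4.401 with the leukocyte marker score as a covariate (4.58 without it). This could not test macrophage RNA as the cause, since the score was nearly balanced. It was -2.72, 4.72 and 3.57 in Control and 4.13, 3.69 and -2.22 in ERI-R. Comparing like libraries argues against it, a choice made after seeing the values. Without leukocyte transcripts, ERI-R 3 averaged 5.77 log2 CPM for epithelial and 1.75 for mesenchymal genes, against 2.17 and 4.61 in Control 1. With them, ERI-R 1 and 2 averaged 5.35 and 5.56 for epithelial genes, against 2.25 and 1.84 in Control 2 and 3. Without ERI-R 3 the epithelial median was 4.34, which argues against that library as the cause. By the criterion first set for a foreign culture, at most 3 counts over the 9 other libraries and at least 10 CPM in every ERI-R library, there were 0 genes. This 0 cannot decide the question, since a culture of the same tissue need not express genes that the others lack. Low levels in libraries with leukocyte transcripts also fail the criterion. Elf5, for example, lay at 0 CPM in Control 1, PAC-R 3 and VIN-R 3, but at 0.479 CPM in PAC-R 1. Every ERI-R library had at least 19.35 CPM of Elf5, which is not one of the leukocyte markers. The source of such low levels in the other libraries was not tested. A version against Control alone was chosen after the 0 was seen. It gave 6 genes, which another origin and an outgrown subclone would both give. The origin of ERI-R therefore stays open, beside a change of state under eribulin, which was not tested.

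Cdkn2a and Cdkn2b, neighbours on chromosome 4, lay near 0 in Control, PAC-R and VIN-R, with at most 0.32 and 0.559 CPM in Control and 0.184 and 1.74 CPM in the 2 lines. Neither these genes nor their neighbour Mtap (89137122 to 89311039 for all 3) were called in PAC-R or VIN-R against Control (Mtap log2 fold changes -1.97 and -2.24, adjusted p = 1.00). With the leukocyte marker score as a covariate Mtap had -2.98 (adjusted p = 0.94) and -3.25 (adjusted p = 0.66), also without a call. Whether lower Mtap is a trait of these lines stays open. In PAC-R 3 and VIN-R 3 all 6 levels of the 3 genes were within 3 times the level of 3 counts, while the flanking Klhl9 lay between 44.0 and 62.5 CPM and Plaa between 99.2 and 134 CPM. A lost or silenced stretch in these 2 libraries is a candidate explanation, and RNA cannot tell these apart. The remaining Mtap in the other 4 libraries of these lines followed Lyz2, with a ratio that varied 1.83-fold against 8.42-fold for Mtap and 7.45-fold for Lyz2, so it may come from macrophage RNA. Depth is argued against, since 3 counts allow at most 0.261 CPM there and Cdkn2a lay at 10.4 CPM or more in every ERI-R library. Control 1, without leukocyte transcripts, had 19.3 CPM of Mtap and 0 of Cdkn2a and Cdkn2b. Of the 3 genes, only Mtap therefore set PAC-R 3 and VIN-R 3 apart from Control 1. In ERI-R against Control edgeR called Cdkn2a and Cdkn2b higher (log2 fold changes 7.53 and 5.35, adjusted p = 0.0058 and 0.036). Mtap was not called there (1.99, adjusted p = 0.37). What this difference says about the origin of ERI-R was not tested.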

How the results depend on the processing

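The score covariate and the 8-library fit were chosen only after the data were seen, and the cause of the changes given here was not tested, except that fits with fewer libraries have fewer degrees of freedom. In the order ERI-R, PAC-R and VIN-R against Control, ERI-R against PAC-R, ERI-R against VIN-R and PAC-R against VIN-R, edgeR called 2732, 0, 0, 2667, 2744 and 0 genes. Fits of the 6 libraries compared gave 1744, 1254 and 1493 in the comparisons with ERI-R. The score covariate gave 4533, 3, 8, 4134 and 4279 in the first 5. DESeq2 gave 24, 36 and 5 in the comparisons without ERI-R. Shared genes rose from 0 to 6 with DESeq2 and 2 with the score, and ranged from 0 to 2 over fits without 1 library (2 without ERI-R 3). Without 1 library of the 2 groups compared, the calls of ERI-R ranged from 1866 to 2868 against Control, 1854 to 2922 against PAC-R and 2040 to 2903 against VIN-R, and were 0 in the other comparisons. The replicate block gave 2666, 0, 0, 2604, 2639 and 0, the 8 libraries 3264, 0, 0, 3287, 3448 and 0. Of the 2732 genes, DESeq2 kept 2703, limma-voom 2582 and the 1.5-fold test 2060. Lists called by camera numbered 4, 6, 2, 8, 5 and 4. With an estimated correlation they were 2, 0, 1, 2, 2 and 1. Directional fry gave 8, 0, 0, 9, 8 and 0 and mixed fry 24, 0, 0, 24, 24 and 0. The 8 libraries gave 8, 6, 8 and 7 in ERI-R and VIN-R against Control, ERI-R against VIN-R and PAC-R against VIN-R, and total counts 7 in the last. Without 1 library they ranged over 4 to 5, 1 (without PAC-R 1) to 12 (without Control 2), 3 (without VIN-R 1) to 11 (without VIN-R 2 or VIN-R 3), 6 to 8, 4 to 7 and 4 (without VIN-R 1) to 13 (without VIN-R 2). The interferon-stimulated list in PAC-R against VIN-R (0.50) reversed to -0.62 without PAC-R 1 and -0.0081 without VIN-R 3, and was 2.92 without VIN-R 2. The replicate block ended the call of the unfolded protein list in ERI-R against PAC-R (median -0.94). Results for single genes, lists and counts of genes called higher were labelled together. Of these, 3844 stayed the same, meaning the same side of the threshold or, for counts, within 1.5 times. A call was lost in 214 and gained in 40, 2 lists reversed, and 13 counts moved by more or to or from 0. Of 104 called named genes in ERI-R against Control, 72 kept their call in every setting. Total counts moved the median of all genes from -0.05 to 0.08 in ERI-R against PAC-R and from -0.03 to 0.09 in ERI-R against VIN-R. The replicate block with total counts moved it from 0.05 to -0.13 in PAC-R and from 0.04 to -0.12 in VIN-R against Control, and the replicate block to -0.13 in ERI-R against Control.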

Other observations

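The SD of window medians was chosen before its result was seen, while the naming of single stretches, the gene families and the Control level of 6 genes were chosen only after.

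In ERI-R against Control 44 gene families were scanned by name, and 11 were kept after their values were seen. The Hox genes were scanned as a single family and count among the 11 as HoxB, HoxA, and HoxC with HoxD. Leaving out single libraries was not run for them. Of 18 keratins 10 were higher and 0 lower, with Krt15 at 34.0 CPM against 0.3098. All 6 HoxB genes were lower, among them Hoxb4 at -4.28, and of 11 HoxA genes 2 were higher (Hoxa13 5.71, Hoxa4 3.02) and 5 lower (Hoxa7 -3.51). Of 11 imprinted genes 5 were higher, including H19 (5.96), Peg3 (5.56) and Phlda2 (4.06), and 2 lower, Sgce (-7.16) and Peg10 (-5.01). Of 6 caveolins and cavins 1 was higher (Cavin4 2.19) and 3 lower (Cav1 -3.84, Cavin2 -2.68, Cavin3 -5.94). Of 9 calcium channel subunits 5 were higher (Cacng4 7.58) and 1 lower (Cacnb2 -6.22). Of 9 desmosome genes 5 were higher (Dsp 4.92, Dsg2 5.79) and 1 lower (Dsc2). Of 17 semaphorins 3 were higher and 9 lower. All 3 placental prolactins were lower (Prl2c3 -5.90, Prl2c2 -5.52). Of 75 ribosomal protein genes 3 were higher and 0 lower, and the 1 tested HoxC or HoxD gene was not called. In PAC-R and VIN-R against Control edgeR called 0 genes of these families.

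Fold changes were not scattered evenly along the chromosomes. In ERI-R, PAC-R and VIN-R against Control the SD of window medians was 0.412, 0.144 and 0.123, above the highest of 1000 shuffles of gene order (0.251, 0.0931 and 0.0840), with p = 0.000999 by permutation, the smallest that 1000 shuffles can give. Regional differences such as copy number are a candidate explanation, but copy number was not measured, and neighbouring genes of a common pathway would give the same. On chromosome 5, 100 genes between 137034993 and 145291278 had a median of 1.63 in ERI-R, with 70 called higher and 2 lower, and medians of 1.22, 1.31 and 1.98 in the 3 ERI-R libraries. With the leukocyte marker score as a covariate the median was 1.58. On chromosome 11, 20 genes between 115268024 and 115823094 had a median of 1.52, with 11 called higher. The cell cycle genes Tyms and Birc5 also lay in raised stretches of 20 genes. That of Tyms, on chromosome 5 between 28317121 and 31054623, had a median of 1.77, with 13 called higher. That of Birc5, on chromosome 11 between 116434094 and 117855743, had a median of 1.38, with 12 called higher. In PAC-R 20 genes on chromosome 1 between 172581758 and 177796511, which include interferon-inducible Ifi genes, had a median of 1.24, and 0.15 with the score. The same stretch had a median of 0.77 in VIN-R, and -0.063 with the score. In VIN-R 40 genes on chromosome 6 between 124958413 and 134566965 had a median of 0.47, with 39 of the same sign. Relative to the Control mean, library medians there were 0.44, 0.31 and 0.56 in VIN-R 1 to 3. They were 0.27, 0.23 and 0.45 in PAC-R 1 to 3 and 0.11, 0.059 and -0.16 in Control 1 to 3, so the stretch was not particular to VIN-R.

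A subclone already present among the parental cells is a candidate explanation for ERI-R. For the 6 genes with at most 3 counts over Control and at least 10 CPM in every ERI-R library, the 95% upper counting limit of the Control level was a median of 1.15% of the ERI-R mean (0.555% to 1.67%). The genes were chosen for their low Control counts, so this sets no bound on the share of such cells, and a subclone and a change of state both stay open.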
